A study of Canis lupus familiaris with 36 samples.

How the data were processed

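Tumour tissue from 35 dogs with lymphoma was profiled on 36 Affymetrix canine expression arrays, 1 per dog except for 1 DLBCL case with 2 arrays. Per the labels' protocols, the tumours were dissociated mechanically and filtered, and biotin-labelled cRNA was hybridised. The deposited values are intensities on a linear scale, 1 per probe set and array, that the authors had summarised and normalized between arrays with GCRMA, per the submitters' processing notes, whose version is not given in the sources used here. The values themselves showed the scale, since they were all positive with a median per array between 5.57 and 6.13 and an upper quartile between 39.5 and 60.1. The design fixed before the data were examined had foreseen either scale, and intensities were floored at 1 and converted to log2. No probe set detection calls were used here. A log2 value of 4, an intensity of 16, served as the minimum, and 32.2% to 35.6% of the probe sets reached it on each array.

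Of the 43035 probe sets, 175 were controls, 29254 were paired with exactly 1 gene symbol in the platform annotation used here, 439 with several and 13167 with none. Through gene identifiers, 27680 of the probe sets with 1 symbol were found in the gene table and none of them needed a newer symbol. They stood for 15115 genes, of which 8254 had several probe sets, and the probe set with the highest mean over all arrays represented each gene. Genes with a log2 value of at least 4 in at least 4 of the 34 tested dogs entered the tests, which left 7500 genes, and 18029 probe sets passed the same filter.

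Groups came from the subtype and phenotype labels. The 2 arrays of the repeated case were averaged, and the NBNT dog was left out of all comparisons of groups because it is a single dog. All tests used R 4.3.3 with limma 3.58.1, with lmFit and eBayes on log2 values, two-sided p-values and Benjamini-Hochberg adjustment over the genes tested, and genes were called at an adjusted p under 0.05. B and T were compared in a fit with 2 group means over 34 dogs. DLBCL against MZL, PTCL against TZL, LBT against TZL, LBT against PTCL, BL against DLBCL, and the difference between the grade steps of the lineages were contrasts in a fit with a mean for each of the 6 subtypes, which shared 1 estimate of the spread. Where every dog of a group lay below the minimum, the fold difference is given as a bound, the mean of the brighter group against the minimum. Where a group mean, but not every dog, lay below the minimum, folds are given with all values below the minimum set to it, a choice made after seeing the data.

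Before the data were examined, 27 lists of genes for lymphoid lineages, cell division, signalling, metabolism and other cell types were fixed, and the 25 lists with at least 5 members tested were compared by limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. The same lists were tested with the correlation estimated from the data, and by permutation of dogs on the mean log2 value over the list, exactly for the comparisons of a pair of subtypes and with 1e+05 resamples for B against T and for the difference between grade steps. Some genes sit in several lists. The genes named in the text followed a rule fixed at the same time, namely the 7 largest differences in each direction among called genes (5 for the difference between grade steps), up to 4 genes with the smallest p from each list described, and 15 genes fixed for every comparison.

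The alternatives fixed before the data were examined were no filter, a stricter filter at log2 6, centring each array on its median, quantile normalization, a variance model with trend and robust settings, array weights, every probe set, the mean of a gene's probe sets, other probe sets of a named gene, both arrays of the repeated case, sex, breed and age as covariates, Golden Retrievers only, the compared groups only, equal weight per subtype, high-grade or low-grade dogs only, leaving out the PTCL dog of intermediate grade, a 2-fold minimum, and leaving out each dog in turn. Added after seeing the data were the 6 arrays that stand apart, taken as those with an actin 3' control of at least 13 on the log2 scale, as a block, left out or alone, centring on bright probe sets, setting log2 values below the minimum to it after the filter, the differences between 3' and 5' probe sets of the actin and GAPDH controls as covariates, leaving out 2 dogs whose sex probe set opposes the label, and 3 alternatives for the principal components.

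The steps were tested on 7500 simulated genes, 100 changed by a log2 difference of 1 and 100 by 2. At size 1, 85% of changed genes were recovered for B against T, 46% for DLBCL against MZL and 36% for PTCL against TZL. The share was 42% for LBT against TZL, 29% for LBT against PTCL, 31% for BL against DLBCL and 23% for the grade steps. At size 2 it was 97%, 84%, 84%, 82%, 68%, 68% and 69% in the same order. Real subtype differences add spread to B against T and may lower its shares. Unchanged genes called numbered 7, 7, 2, 14, 6, 9 and 6, and unchanged lists 0. Other splits of the dogs, up to 100 per comparison, called up to 18 lists, so this 0 is no assurance.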

Results

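Gene expression was measured in lymphoma tissue from 35 dogs with 36 arrays of 43035 probe sets each. The labels gave every tumour a phenotype and a subtype. The B phenotype held 17 dogs, of which 10 had diffuse large B-cell lymphoma (DLBCL), 5 had marginal zone lymphoma (MZL) and 2 carried the label BL. The T phenotype also held 17 dogs, of which 4 carried the label LBT, 4 had peripheral T-cell lymphoma (PTCL) and 9 had T-zone lymphoma (TZL). A single further dog, labelled NBNT, entered no comparison of groups. Every dog was a separate case, and the 2 arrays of the same DLBCL case, replicates 6 and 7, were averaged and counted once. The labels listed 15 males and 20 females. Golden Retrievers made up 6 of the DLBCL, 4 of the MZL, 1 of the BL, 3 of the LBT, 1 of the PTCL and 8 of the TZL dogs. Grade followed subtype, with MZL and TZL labelled low grade and the other tested subtypes high grade, except for 1 PTCL dog of intermediate grade, so that an effect of grade cannot be separated from one of subtype. Median intensities per array lay between 5.57 and 6.13, and 32.2% to 35.6% of probe sets reached the minimum of 16. The number of arrays limits the precision of every comparison.

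The first principal component separated the lineages. It held 31.0% of the variance, and the B arrays scored between -61.4 and -13.1 on it while the T arrays scored between 2.37 and 68.3. The mean of the T dogs exceeded that of the B dogs by 87.5 (two-sided permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 3e-05 over 3 components). The second component, with 16.6% of the variance, did not separate the phenotypes (permutation p = 0.6, adjusted p = 0.88). The 2 arrays of the repeated DLBCL case correlated at 0.990 across genes, against 0.864 to 0.956 over 54 other pairs of DLBCL arrays.

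**Figure D1:**
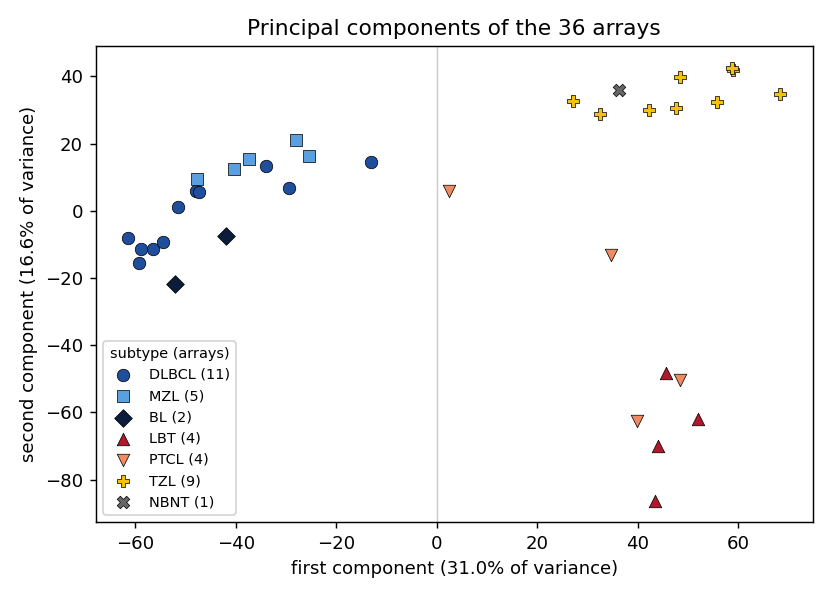
Scores of the 36 arrays on the first (horizontal) and second (vertical) principal component of the log2 values of the 7500 genes tested, coloured by subtype. All B arrays lie at -13.1 or lower on the first component and all T arrays at 2.37 or higher.

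A set of 6 arrays stood apart from the other 30 in a way that the labels did not record. These were DLBCL replicates 4 and 9, PTCL replicate 3 and TZL replicates 1, 2 and 7. Their 3' control for actin lay between 14.0 and 14.4 on the log2 scale, against 10.8 to 12.5 on the other arrays. Their scores on the third component lay between -55.9 and -16.8, against -7.64 to 26.7. With limma, 1677 genes differed between the set and the other arrays within subtypes, 709 of them higher and 968 lower in the set. The set held 2 DLBCL, 1 PTCL and 3 TZL dogs and no MZL, BL or LBT dog, so each count of called genes below is also given with the set as a block in the fit and without its arrays, and so are the list calls that changed.

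**Figure D2:**
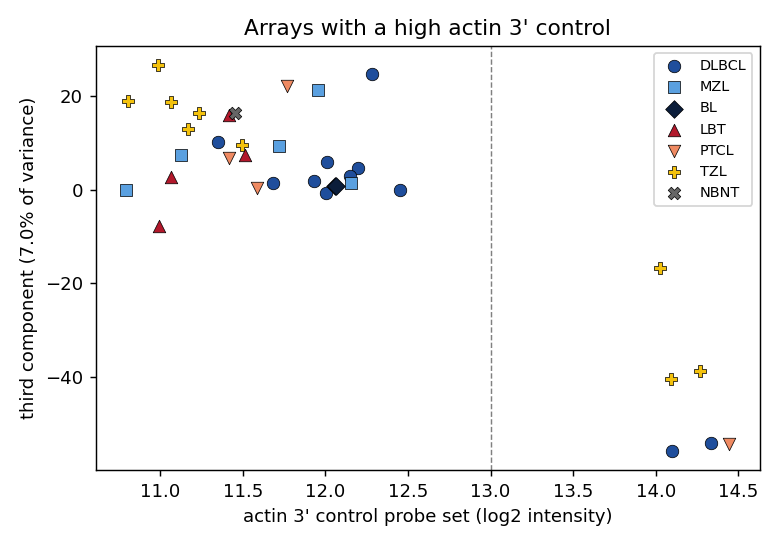
Log2 intensity of the actin 3' control (horizontal) against the score on the third principal component (vertical) for the 36 arrays, coloured by subtype, with a dashed line at a log2 intensity of 13. The 6 arrays to the right of the line lie at -16.8 or lower on the third component, and all others lie at -7.64 or higher.

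The comparison of the B with the T phenotype asks which genes follow the lineage of the tumour. Genes of T cell identity were far lower in the B lymphomas. TRAT1, an adaptor of the T cell receptor, had a mean log2 intensity of 4.10 ± 1.33 in B and 10.87 ± 1.44 in T (SD, n = 17 each). Since the B dogs lay near or below the minimum intensity for most of these genes, folds in this paragraph are given with every value below the minimum set to it, which was chosen after the data were seen. By this measure TRAT1 was 78.1-fold lower in B, the costimulatory receptor CD28 31.0-fold, the kinase PRKCQ 37.2-fold, the transcription factors GATA3 26.4-fold and LEF1 28.2-fold, and the surface glycoprotein CD52 34.8-fold. CD40LG, the ligand through which helper T cells stimulate B cells, was below the minimum in every B dog and at least 25.2-fold lower there. Among the genes higher in B, the lipid phosphatase PLPP3 differed 24.3-fold (log2 9.21 ± 1.27 against 4.14 ± 1.44 before that step), and BLNK, an adaptor of the B cell receptor, had a log2 difference of 4.09. NAPSA was 15.8-fold, OSBPL6 14.3-fold, KLHL14 7.55-fold and SLC38A11 6.46-fold higher in B, and ASIC5, below the minimum in every T dog, was at least 7.09-fold higher. For these 14 genes the limma adjusted p, from values as measured, ranged from 2.25e-17 for CD28 to 8.62e-07 for BLNK.

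All 19 measured genes of the T cell lineage list were lower in B, with a median log2 difference of -4.15 (camera adjusted p = 2.9e-21, and adjusted p = 0.0053 with an estimated correlation). All 14 genes of the B cell lineage list were higher in B, with a median of 3.33, among them the kinase BLK (3.42, SE 0.35), the surface receptor CD22 (3.14, SE 0.37) and the transcription factor EBF1 (3.74, SE 0.49). Camera called this list (adjusted p = 9.9e-09), although not with an estimated correlation (adjusted p = 0.22). Of the 15 genes of B cell receptor signalling, 11 were higher and 2 lower in B, with PLCG2 at 3.69 (SE 0.50) and SYK at 3.44 (SE 0.52), at an adjusted p = 6.1e-04 with camera and adjusted p = 0.41 with an estimated correlation. Of the 22 genes of MYC targets and ribosome biogenesis, 20 were higher in B, with a median of 0.94 (adjusted p = 3.3e-09, and adjusted p = 0.027 with an estimated correlation). Among them were the nucleolar proteins NOP56 (1.41, SE 0.13) and DKC1 (1.40, SE 0.15), and MYC itself was 2.31-fold higher in B (adjusted p = 0.000798). Genes of resting and naive lymphocytes were lower in B in 9 of 12 cases, including the receptor IL7R (-5.08, SE 0.42) and CD27 (-4.74, SE 0.54), with camera adjusted p = 2e-04 and adjusted p = 0.15 with an estimated correlation. T cell co-inhibition and helper genes were lower in 7 and higher in 2 of 12 cases, with SH2D1A at -4.18 (SE 0.40) and the receptor TNFRSF18 at least 5.19-fold lower in B, where every dog was below the minimum (adjusted p = 0.026, and adjusted p = 0.19 with an estimated correlation). Of the 26 DNA replication genes 11 were higher in B, including RFC2 (1.0, SE 0.12), and of the 25 mitosis genes 6 were higher, including MYBL2 (2.05, SE 0.46). The adjusted p for replication was 0.010 with camera and adjusted p = 0.81 with an estimated correlation, and for mitosis adjusted p = 0.026 and adjusted p = 0.83. By permutation of dogs it was 0.034 for replication and 0.10 for mitosis. Among high-grade dogs the median difference turned to -0.29 for mitosis (camera adjusted p = 0.75) and -0.14 for replication (adjusted p = 0.95), while among low-grade dogs, MZL against TZL, it was 1.20 (adjusted p = 6e-04) and 0.91 (adjusted p = 2e-04). Adjusted over the list alone, the counts were 10 for replication and 5 for mitosis, and unchanged for the other lists of this paragraph.

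MS4A1, the CD20 antigen, was 10.4-fold higher in B (adjusted p = 2.01e-05), with 11.40 ± 0.44 in B and 8.02 ± 2.50 in T on the log2 scale (SD, n = 17 each). CD79A, a chain of the B cell receptor, was 3.22-fold higher (adjusted p = 0.0152). CD3E, a chain of the T cell receptor complex, was 24.3-fold lower in B (adjusted p = 8.4e-08), and the co-receptor CD4 was 4.73-fold lower (adjusted p = 0.000489). The co-receptor CD8A had a log2 difference of -1.60 (adjusted p = 0.0709), and DNTT, the template-independent polymerase of immature lymphocytes, one of 1.26 (adjusted p = 0.0519). Leaving out 1 dog brought CD8A under 0.05 in 3 of 34 cases (adjusted p down to 0.048) and DNTT in 11 (down to 0.0259). The apoptosis inhibitor BCL2 was 2.79-fold lower in B (adjusted p = 0.000772) and the repressor BCL6 5.71-fold lower (adjusted p = 6.65e-05). PTPRC, the leukocyte common antigen CD45, had a difference of 0.45 (adjusted p = 0.502), which turned to -1.07 among the high-grade dogs (adjusted p = 0.00919). The MYC difference turned to -0.41 within the 6 arrays of the set (adjusted p = 0.769). Of the 15 genes fixed for every comparison, 12 had a probe set paired with them here and 11 passed the filter.

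Limma called 3486 of 7500 genes between B and T, 1814 higher and 1672 lower in B, and 1435 of them differed at least 2-fold. With the array set as a block 3604 genes were called, without it 3212, and within the set alone, with 2 B and 4 T dogs, 149. Camera called 8 of 25 lists, of which the T cell lineage list and the list of MYC targets and ribosome biogenesis held with an estimated correlation. The call of the mitosis list was lost when any of 5 dogs was left out (DLBCL replicate 4 and TZL replicates 1, 4, 5 and 8), with adjusted p up to 0.074. With values below the minimum set to it, the lists of mitosis and of T cell co-inhibition were not called (adjusted p = 0.050 and 0.051). With equal weight per subtype mitosis was not called (adjusted p = 0.11), among low-grade dogs co-inhibition was not (0.13), and within the array set neither was (0.050 and 0.096). With the 3' to 5' differences of the actin and GAPDH controls as covariates, a setting chosen after the data were seen, mitosis (median 0.33, adjusted p = 0.41) and replication (0.37, adjusted p = 0.12) lost their call and MHC class II gained one (adjusted p = 0.019). Without TZL replicate 5 or 6 the number of replication genes called was 7. By permutation of dogs 7 further lists were called, all with lower scores in B except oxidative phosphorylation (adjusted p = 0.040). The others were immature lymphoid genes (1.8e-04), endothelium (1.9e-04), neutrophil and mast cell genes (0.0039), p53 targets (0.015), cell death regulators (0.034) and the cytotoxic list (0.044).

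**Figure D3:**
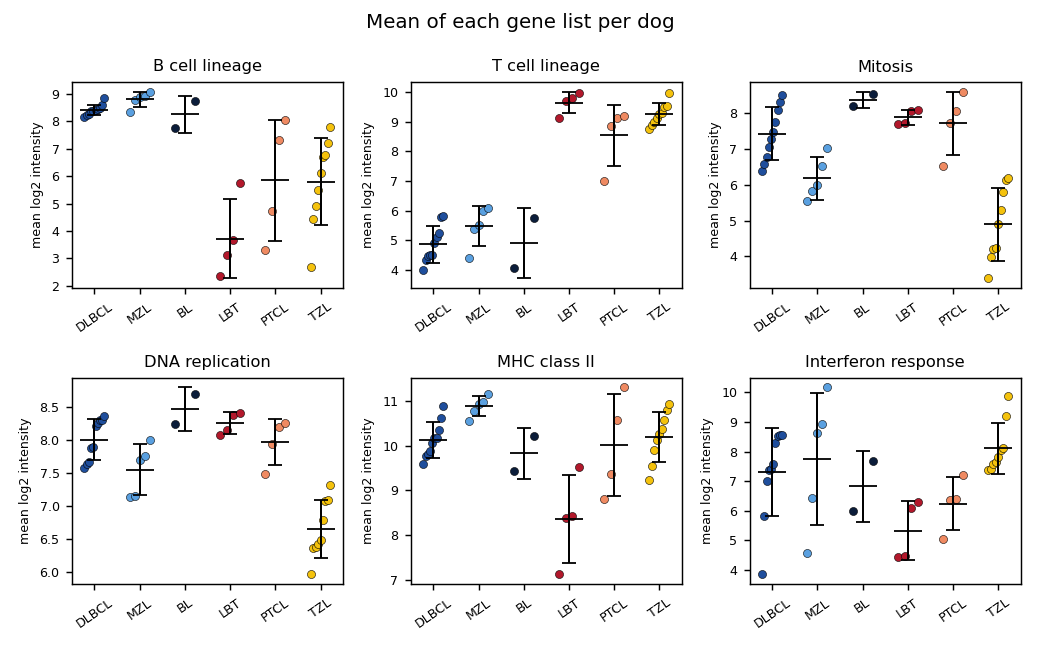
Mean log2 value over the measured members of 6 gene lists (vertical) for each tested dog, by subtype (horizontal), with the mean ± SD of each subtype as bars. The T dogs lie at 7.01 or higher for the T cell lineage list and the B dogs at 6.10 or lower, while the mitosis scores average 4.91 in TZL and 7.89 in LBT.

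DLBCL and MZL are B lymphomas of high and of low grade in these labels, and their comparison asks what separates them. No single gene was called. The 25 mitosis genes had a median log2 difference of 1.31, a list called by camera but not with an estimated correlation (adjusted p = 0.33), and 16 of them passed when adjusted over the list alone and 0 over all genes. The mean mitosis score was 7.42 ± 0.74 in the 10 DLBCL dogs and 6.18 ± 0.60 in the 5 MZL dogs (SD). The difference between 3' and 5' probe sets of the RNA quality controls was also higher in DLBCL, by 1.85 for actin (exact permutation p = 0.018) and by 0.48 for GAPDH (exact permutation p = 0.014), with adjusted p = 0.090 for both over 20 tests chosen after the data were seen. Outside the array set it was higher by 1.20 and 0.58 (adjusted p = 0.054 for both). With both controls as covariates the mitosis median was 0.83 and the list was still called (adjusted p = 3.7e-11), so that an effect of RNA quality on part of the difference was not excluded. The spindle protein ASPM had a difference of 2.87 (SE 0.60, adjusted p = 0.0565) and the kinesin KIF23 one of 1.92 (SE 0.46, adjusted p = 0.0633). Genes of antigen presentation by MHC class II had a median difference of -0.70 over 14 genes, with -2.07 (SE 0.57) for CIITA, the master regulator of the pathway (adjusted p = 0.114), and genes of resting and naive lymphocytes one of -0.83 over 12 genes, with -2.43 (SE 0.74) for CD27 (adjusted p = 0.156). Without DLBCL replicate 3 the adjusted p was 0.0275 for ASPM, 0.0379 for KIF23, 0.0472 for CIITA and 0.0379 for CD27. Without MZL replicate 2 or DLBCL replicate 10 ASPM (adjusted p = 0.046 and 0.0254) and KIF23 (0.0447 and 0.0463) were also called, and ASPM without DLBCL replicate 9 (adjusted p = 0.0409). No other gene of these 3 lists was called without 1 of these dogs, and 1 oxidative phosphorylation gene was called without DLBCL replicate 3.

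Camera called the mitosis list at adjusted p = 1e-15, which became adjusted p = 0.33 with an estimated correlation and 0.038 in the exact permutation test of dogs on the list score. The MHC class II list had adjusted p = 3e-04, adjusted p = 0.52 with an estimated correlation and 0.035 by exact permutation, with 1 gene lower when adjusted over the list alone. The resting and naive lymphocyte list had adjusted p = 0.0021, adjusted p = 0.33 with an estimated correlation and 0.042 by exact permutation, with 3 genes lower when adjusted over the list alone. DNA replication had a median of 0.41 (adjusted p = 7.8e-07, adjusted p = 0.33 with an estimated correlation, 0 genes adjusted over the list alone), and oxidative phosphorylation one of 0.21 (adjusted p = 1.3e-04, adjusted p = 0.39 with an estimated correlation, 3 genes adjusted over the list alone). The 4 other lists called were T cell lineage (-0.77, adjusted p = 0.042, adjusted p = 0.71 with an estimated correlation), MYC targets and ribosome biogenesis (0.14, adjusted p = 0.042, adjusted p = 0.66 with an estimated correlation), the follicle list (-0.83, adjusted p = 0.039, adjusted p = 0.33 with an estimated correlation) and glycolysis and hypoxia (-0.29, adjusted p = 0.039, adjusted p = 0.33 with an estimated correlation). Leaving out single dogs ended each of those 4 calls, by 9, 8, 7 and 6 different dogs in that order, with adjusted p up to 0.23, 0.20, 0.14 and 0.12. By exact permutation the adjusted p was 0.085 for replication, 0.24 for oxidative phosphorylation, 0.23 for T cell lineage, 0.57 for MYC targets and 0.035 for the follicle and the glycolysis lists. It was 0.017 for B cell receptor signalling and 0.042 for B cell lineage, both with lower scores in DLBCL and not called by camera (adjusted p = 0.13 and 0.39). With the 3' to 5' controls as covariates T cell lineage (0.20) and glycolysis (0.29) were not called. Without the array set the MYC targets (adjusted p = 0.052), the follicle list (adjusted p = 0.052) and glycolysis (adjusted p = 0.13) were not called. With covariates T cell lineage (adjusted p = 0.16), MYC targets (adjusted p = 0.11) and glycolysis (adjusted p = 0.10) lost their call, and with the stricter filter T cell lineage (0.059), MYC targets (0.076) and the follicle list (0.076). The follicle list was also lost with array weights (adjusted p = 0.086) and, as was T cell lineage (0.055), with the mean of a gene's probe sets (0.053), and MYC targets with the compared groups only (0.061). T cell lineage (0.37) and MYC targets (0.054) were lost with values below the minimum set to it, and without the 2 dogs of opposed sex probe set T cell lineage (0.075), the follicle list (0.082) and glycolysis (0.092).

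Limma called 0 of 7500 genes between DLBCL and MZL, with 977 at an unadjusted p under 0.05 against 375 by chance, and with array weights it called 378. With the array set as a block 0 genes were called, and without its 6 arrays 19. With values below the minimum set to it 39 were called. Without DLBCL replicate 3 the count was 68 and without DLBCL replicate 10 it was 43.

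PTCL and TZL are T lymphomas that the labels place at high or intermediate and at low grade. Cell division genes were higher in PTCL by single-gene tests, while their lists were called by camera but not with an estimated correlation (adjusted p = 0.092 for mitosis and for replication). All 25 mitosis genes were higher, by a median log2 difference of 2.90, including the centromere protein CENPF (3.98, SE 0.56, adjusted p = 1.9e-05), the kinesin KIF11 (3.66, SE 0.57) and the kinase CDK1 (2.71, SE 0.43). Of the 26 DNA replication genes 19 were higher over all genes and 24 when adjusted over the list alone, among them the helicase subunits MCM5 (2.30, SE 0.37) and MCM6 (1.34, SE 0.21). DPP4, the CD26 ectopeptidase, was 43.9-fold higher in PTCL (log2 9.96 ± 1.27, n = 4) than in TZL (4.50 ± 0.69, n = 9, SD), with limma adjusted p = 1.53e-07. CCDC3 was 56.5-fold lower in PTCL (adjusted p = 5.63e-08), and 36.2-fold without PTCL replicate 3. IL2, the T cell growth factor, had a log2 difference of -4.89 (adjusted p = 0.000102), but PTCL replicate 1 lay at 8.79 against 1.88 to 2.52 in the other PTCL dogs. The difference was -6.54 without that dog and -4.24 without PTCL replicate 3, and 11.7-fold over all dogs with values below the minimum set to it.

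Further genes higher in PTCL were below the minimum in every TZL dog, so that only a bound can be given. These were AMPH at least 12.4-fold, SNAP91 at least 12.3-fold, ANK3 at least 10.1-fold, FBP1 at least 9.54-fold and NSG1 at least 9.14-fold (adjusted p = 2.2e-05 or smaller for each). PTCL dogs varied in these genes. As measured, the log2 difference rose without PTCL replicate 4 to 7.10 for AMPH, 6.74 for SNAP91, 6.58 for ANK3 and 6.35 for NSG1. It fell to 4.28 for AMPH without PTCL replicate 2, and without PTCL replicate 3 to 4.39 for SNAP91, 4.42 for ANK3, 3.82 for NSG1 and 4.00 for FBP1. GTSF1 was at least 25.6-fold higher in PTCL (adjusted p = 0.0112), although 1 PTCL dog had a log2 value of 2.34 and without the array set the adjusted p was 0.118. Without PTCL replicate 2 or 3 GTSF1 was not called (adjusted p = 0.0625 and 0.0651), and without PTCL replicate 4 its log2 difference was 8.30. Of the genes lower in PTCL, GLYAT, a glycine acyltransferase, was below the minimum in every PTCL dog and at least 15.0-fold lower. TCEA3 was 28.6-fold lower. With values below the minimum set to it, since the PTCL means lay below it, the difference was 19.1-fold for GBP5, an interferon-inducible GTPase, 16.8-fold for KRTCAP3 and 7.61-fold for RCN3. CD8A was below the minimum in all PTCL dogs and at least 5.24-fold lower (adjusted p = 0.0144), but TZL spanned log2 2.85 to 11.0. PTPRC was 6.44-fold higher in PTCL (adjusted p = 0.0153), 3.94-fold without TZL replicate 5 (0.00117). Neither was called without PTCL replicate 2 (0.0576 and 0.0678), nor CD8A without the array set (0.0673).

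Interferon response genes had a median log2 difference of -1.97, and -1.33 without PTCL replicate 3, with 3 of 15 lower in PTCL, namely USP18 (-2.90, SE 0.80), IRF7 (-2.68, SE 0.90) and ISG15 (-3.37, SE 1.14), and again 3 when adjusted over the list alone. IRF7 lost its call in 10 of 13 cases of 1 dog left out (adjusted p up to 0.157), ISG15 in 9 (up to 0.23) and USP18 without PTCL replicate 3 (adjusted p = 0.083), and without the array set 0 of the 15 were called. The number called was 0 without PTCL replicate 3 and 1 without PTCL replicates 1 or 2 or TZL replicates 1, 4, 5, 6, 7 or 8. The ISG15 difference was -2.35 without PTCL replicate 3 and -4.17 without PTCL replicate 4. Of 14 cytotoxic and NK genes 3 were lower, including the death ligand FASLG (-3.42, SE 0.55) and CST7 (-2.37, SE 0.52), and adjusted over the list alone 5 were lower and 1 higher. Of 18 macrophage and dendritic cell genes 4 were higher, such as the lipopolysaccharide co-receptor CD14 (2.37, SE 0.36), and 1 was lower, the costimulator CD80 (-2.31, SE 0.56), with 6 and 1 adjusted over the list alone, and 3 in all without PTCL replicate 2 and 2 without PTCL replicate 3. Of 21 oxidative phosphorylation genes 6 were higher, for example COX4I1 (0.50, SE 0.13), 3 without PTCL replicate 3 and 7 when adjusted over the list alone, and of 19 T cell lineage genes 2 were lower, SIT1 (-2.73, SE 0.54) and UBASH3A (-2.84, SE 0.57). UBASH3A was at -3.80 without PTCL replicate 1 and at -2.22 without PTCL replicate 2. The camera adjusted p was 3.8e-25 for mitosis and 3.9e-15 for replication, and adjusted p = 0.092 with an estimated correlation for both. It was 2.4e-04 for interferon response, 0.0011 for the cytotoxic list and 0.0025 for oxidative phosphorylation, and adjusted p = 0.54 with an estimated correlation for each of the 3. It was 0.022 for the macrophage list and 0.029 for T cell lineage, with adjusted p = 0.74 and adjusted p = 0.69 with an estimated correlation. By exact permutation of dogs on the list scores, mitosis, replication and interferon response each had an adjusted p of 0.012, against 0.063 for the cytotoxic list, 0.12 for oxidative phosphorylation, 0.22 for T cell lineage and 0.51 for the macrophage list. It was 0.017 for T cell co-inhibition, which had a higher score in PTCL and was not called by camera (adjusted p = 0.066).

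Limma called 1025 of 7500 genes between PTCL and TZL, 570 higher and 455 lower in PTCL. With the array set, which held 1 PTCL and 3 TZL dogs, as a block 1182 genes were called, and without it 556. The macrophage list lost its call without the set (adjusted p = 0.075), with the stricter filter (0.21), array weights (0.081), covariates (0.052) and the compared groups only (0.063), and T cell lineage with quantile normalization (0.053). Removing PTCL replicate 4 moved the cytotoxic median from -1.76 to -2.49, and without PTCL replicate 2 the count of genes was 587. Leaving out PTCL replicate 4 or TZL replicate 8 ended the call of the T cell lineage list (adjusted p up to 0.81), and leaving out PTCL replicate 4 or TZL replicate 5 that of the macrophage list (adjusted p up to 0.35).

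The comparison of LBT with TZL sets a high-grade against a low-grade T subtype. Several genes were bright in every LBT dog and below the minimum in every TZL dog. GTSF1 was at least 148-fold higher in LBT (log2 11.21 ± 0.37, SD, n = 4), the matrix protein SMOC2 at least 129-fold (11.01 ± 0.64), AMPH at least 61.7-fold, KHDRBS3 at least 61.3-fold, the membrane adaptor ANK3 at least 52.9-fold and NSG1 at least 41.0-fold. DPP4 was 141-fold higher in LBT, with 11.65 ± 2.20 against 4.50 ± 0.69 in the 9 TZL dogs, and 78.0-fold without LBT replicate 1 and 263-fold without LBT replicate 4. CCDC3, CSTA, IFGGC1 and IL2 had LBT means below the minimum. With values below the minimum set to it, CCDC3 was 77.2-fold lower in LBT, the protease inhibitor CSTA 42.3-fold, IFGGC1 29.1-fold and IL2 23.0-fold. As measured, the log2 difference of CCDC3 was -7.57 (limma adjusted p = 1.51e-10), and -8.53 without LBT replicate 3. RBP4, the plasma carrier of retinol, was at least 51.2-fold lower, the lymphoid chemokine CCL21 at least 25.0-fold and GLYAT at least 15.0-fold, all below the minimum in every LBT dog. As measured, RBP4 differed by -7.18, and by -7.92 without TZL replicate 9. The limma adjusted p of these 14 genes was at most 0.000285.

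Mitosis genes were higher in LBT in all 25 cases, by a median of 3.10, with KIF11 at 3.84 (SE 0.57) and CDK1 at 3.23 (SE 0.43), and 23 of 26 DNA replication genes were higher, with MCM5 at 3.60 (SE 0.37), 25 when adjusted over the list alone. Of 21 oxidative phosphorylation genes 12 were higher, including NDUFB5 (1.22, SE 0.21), and 17 when adjusted over the list alone. The transcription factor MYB was at least 18.9-fold higher in LBT, and the T cell regulators IKZF2 (6.04, SE 0.73) and TOX (3.79, SE 0.82) were higher. Their lists were not called by camera, the immature lymphoid list of MYB with 1 gene higher and 3 lower of 5 (median -1.44, adjusted p = 0.86) and the co-inhibition list of the others with 4 higher and 1 lower of 12 (adjusted p = 0.46, and 0.032 by exact permutation). Only 2 immature lymphoid genes were called without any of 7 dogs (LBT replicates 1 and 2 and TZL replicates 2, 3, 6, 7 and 9). Of 14 MHC class II genes 9 were lower, including DLA-DMB (-3.66, SE 0.50) and the invariant chain CD74 (-2.28, SE 0.32), and 11 when adjusted over the list alone. Of 15 interferon response genes 9 were lower, including USP18 (-4.21, SE 0.80) and MX2 (-4.48, SE 1.21), and 11 when adjusted over the list alone. Cytotoxic and NK genes were lower in 7 and higher in 1 of 14. FASLG was at least 8.46-fold, CD8B 8.73-fold and CD8A 5.24-fold lower (CD8A in TZL 2.85 to 11.0). Of the B cell lineage genes 7 of 14 were lower, but 0 were called without LBT replicate 1, 3 without LBT replicate 2 and 4 without LBT replicate 3. They included CD79A (-3.07, SE 0.83) and FCRLA (-3.74, SE 1.08), both of which lost their call without LBT replicate 1 (-2.36, adjusted p = 0.052, and -2.90, adjusted p = 0.0698). CD79A was at -2.39 without LBT replicate 3 and -3.97 without LBT replicate 4, and FCRLA at -4.44 without TZL replicate 5 and -4.74 without LBT replicate 4. DLA-DMB was at -3.05 without LBT replicate 1, and MX2 lay between -3.75 (without LBT replicate 2) and -5.23 (without LBT replicate 4), with -3.86 without LBT replicate 1 and -5.09 without LBT replicate 3. PTPRC was 7.32-fold higher in LBT (adjusted p = 0.00436), and 4.48-fold without TZL replicate 5 (adjusted p = 0.000146).

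Camera called 12 of 25 lists between LBT and TZL, none of which held with an estimated correlation. The adjusted p was 5.2e-16 for mitosis, 7.1e-12 for replication and 4.8e-08 for MHC class II, with adjusted p = 0.26 with an estimated correlation for each. It was 7.8e-06 for oxidative phosphorylation, 3.8e-05 for interferon response, 5.5e-04 for the cytotoxic list and 6.8e-04 for B cell lineage, with adjusted p = 0.31, 0.40, 0.37 and 0.40 with an estimated correlation. Genes of NF-kappaB targets were lower in 5 of 14 cases (adjusted p = 0.0036, and adjusted p = 0.34 with an estimated correlation), such as BCL2A1 (-2.34, SE 0.36). The plasma cell list was lower in 5 of 13 cases (adjusted p = 0.0084, and adjusted p = 0.26 with an estimated correlation), such as JCHAIN (-2.80, SE 0.63). B cell receptor signalling was lower in 6 of 15 (adjusted p = 0.0056, and adjusted p = 0.40 with an estimated correlation) and immediate early genes in 5 of 16 cases (adjusted p = 0.0070, and adjusted p = 0.42 with an estimated correlation), such as JUNB (-3.12, SE 0.90), which was at -3.77 without LBT replicate 4 and not called without LBT replicate 1 (adjusted p = 0.0588). Without LBT replicate 1 the number of genes called was 1 for B cell receptor signalling, 1 for immediate early genes and 3 for NF-kappaB targets. Without LBT replicate 2 it was 3 for B cell receptor signalling and 2 for NF-kappaB targets, which had 3 without LBT replicate 3. The neutrophil and mast cell list, with 1 of 7 genes lower, had adjusted p = 0.048 and adjusted p = 0.40 with an estimated correlation, and lost its call without any of 9 dogs (adjusted p up to 0.11) and with the array set as a block (adjusted p = 0.081), while 3 of its genes were called without TZL replicate 5 or 8 and 2 without TZL replicate 6. Adjusted over the list alone, the counts of lower genes were 9 for B cell lineage, 8 for the cytotoxic list, 7 for B cell receptor signalling, 6 for the plasma cell list, 5 each for NF-kappaB targets and immediate early genes and 3 for the neutrophil and mast cell list. By exact permutation of dogs, the adjusted p was 0.0070 for mitosis, replication, interferon response, oxidative phosphorylation and the plasma cell list, 0.010 for MHC class II and the cytotoxic list, 0.016 for NF-kappaB targets, 0.041 for the neutrophil and 0.043 for the immediate early list, against 0.084 for B cell lineage and 0.070 for B cell receptor signalling. Resting and naive lymphocyte genes (0.013) and cell death regulators (0.021), both with lower scores in LBT, were called by permutation and not by camera (adjusted p = 0.084 and 0.14).

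Limma called 2259 of 7500 genes between LBT and TZL, 1332 higher and 927 lower in LBT. With the array set, which held 3 TZL dogs, as a block 2376 genes were called, and without it 2124. Without it the neutrophil and mast cell list was not called (adjusted p = 0.13), as in 9 other settings beside the block (adjusted p from 0.053 without a filter to 0.11 with values below the minimum set to it), while the resting and naive lymphocyte list was (adjusted p = 0.041). TZL dogs served in both this comparison and the one with PTCL, so these comparisons share their chance values and their results are not set side by side.

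LBT and PTCL, the T subtypes of higher grade, differed in few genes. SLC16A10, an amino acid transporter, had log2 values of 7.62 ± 0.66 in LBT and 3.71 ± 2.18 in PTCL (SD, n = 4 each, limma adjusted p = 9.52e-05). With values below the minimum set to it, because a mean lay below it, SLC16A10 was 7.68-fold, FNBP1L 15.6-fold and CCDC30 8.87-fold higher in LBT, and the elongation factor ELL2 was 7.35-fold and LPGAT1 3.53-fold lower. As measured, SMOC2 was 17.9-fold, the actin-severing protein DSTN 14.5-fold, KHDRBS3 14.2-fold and SH3GL3 13.5-fold higher in LBT. Genes lower in LBT included the lectin LGALS3 (8.20-fold), the stress-response factor NFE2L2 (7.83-fold), PTPN12 (5.85-fold) and the integrin ITGAX, also called CD11c, which was at least 4.38-fold lower. MHC class II genes were lower in LBT in 3 of 14 cases, namely DLA-DMB (-2.57, SE 0.59), DLA-DQA1 (-1.69, SE 0.38) and CD74 (-1.62, SE 0.38), and in 11 when adjusted over the list alone.

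These values rested on few dogs. The number of MHC class II genes called was 0 without LBT replicate 1 or PTCL replicate 1 or 4, 1 without LBT replicate 2, 8 without PTCL replicate 2 and 9 without LBT replicate 4. Of the 16 genes just named, SLC16A10, SMOC2, DSTN and LPGAT1 kept their call with any of the 8 dogs left out (adjusted p up to 0.00155, 0.0498, 0.0192 and 0.0197). Without PTCL replicate 4 none of the 12 others was called, with adjusted p from 0.0554 for CCDC30 to 0.163 for KHDRBS3, ELL2 and DLA-DMB. The number of dogs that ended a call when left out was 5 for KHDRBS3, NFE2L2, ITGAX, DLA-DQA1 and CD74, 4 for ELL2, LGALS3 and DLA-DMB, 3 for FNBP1L and SH3GL3, 2 for PTPN12 and 1 for CCDC30. As measured, the fold lay between 9.95 (without PTCL replicate 1) and 30.1 (without PTCL replicate 3) for SLC16A10, 6.65 (without PTCL replicate 4) and 42.2 (without PTCL replicate 2) for SMOC2, and 6.90 (without PTCL replicate 1) and 42.2 (without PTCL replicate 3) for KHDRBS3, with 7.70 without PTCL replicate 4. It lay between 8.09 (without LBT replicate 1) and 36.2 (without PTCL replicate 2) for SH3GL3, with 8.10 without PTCL replicate 4, and between 12.7 (without LBT replicate 1) and 33.2 (without LBT replicate 4) for FNBP1L. It was 23.9 for CCDC30 without PTCL replicate 2, 6.15 for ELL2 without PTCL replicate 4, 9.87 for LPGAT1 without LBT replicate 4 and 3.79 for PTPN12 without LBT replicate 3. For DLA-DMB it was 10.4 without PTCL replicate 2, 3.88 without LBT replicate 1 and 3.82 without PTCL replicate 4.

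Camera called the MHC class II list, with a median of -1.70, at adjusted p = 1e-15 (adjusted p = 0.11 with an estimated correlation), the macrophage and dendritic cell list, with a median of -1.78, at 8.2e-10 (adjusted p = 0.19 with an estimated correlation, 1 of 18 genes lower and 7 adjusted over the list alone) and B cell lineage, with a median of -1.97, at 3.3e-08 (adjusted p = 0.19 with an estimated correlation, 0 genes). T cell lineage had a median of 0.83 (adjusted p = 5.9e-05, adjusted p = 0.23 with an estimated correlation, 0 genes and 5 adjusted over the list alone). B cell receptor signalling, NF-kappaB targets, germinal centre, neutrophil and stroma genes had medians from -2.04 to -1.23 and adjusted p from 2.9e-05 to 0.0035, with adjusted p = 0.19 for the first 4 and 0.29 for stroma with an estimated correlation. Immediate early genes had a median of -1.01 (adjusted p = 5.9e-04), oxidative phosphorylation 0.24 (adjusted p = 6.3e-04) and the plasma cell list -0.53 (adjusted p = 0.047), with adjusted p = 0.29, 0.29 and 0.26 with an estimated correlation. No gene of these 8 lists was called over all genes, and adjusted over the list alone 3 NF-kappaB targets, 2 neutrophil, 2 oxidative phosphorylation genes and 1 plasma cell gene passed. The exact permutation test of dogs could hardly call a list here, since its smallest possible p of 0.029 would have to be reached by 15 of the 25 lists, and the smallest adjusted p was 0.27. Without the array set the stroma (adjusted p = 0.085) and plasma cell lists (adjusted p = 0.076) were not called, while DNA replication (adjusted p = 0.024) and interferon response (adjusted p = 0.018) were. With the set as a block the plasma cell list was not called (adjusted p = 0.11) and replication was (adjusted p = 0.020). Leaving out PTCL replicate 3 ended the call of the stroma list (adjusted p = 0.054) and leaving out PTCL replicate 1 that of immediate early genes (adjusted p = 0.097), and any of 6 dogs ended that of the plasma cell list (adjusted p up to 0.21). The plasma cell list also lost its call with the stricter filter (0.052), quantile normalization (0.065), covariates (0.42), centring on bright probe sets (0.060), values below the minimum set to it (0.15) and without the 2 dogs of opposed sex probe set (0.062). The neutrophil list lost it with the stricter filter (0.15) and covariates (0.095). With the 3' to 5' controls as covariates the plasma cell list was not called (0.10) and replication was (0.0095). The number of macrophage genes called was 0 without LBT replicates 1, 2 or 3 or PTCL replicate 4, 2 without PTCL replicate 1, 3 without LBT replicate 4 and 4 without PTCL replicate 2. For T cell lineage it was 1 without LBT replicate 2 or 3, 2 without PTCL replicate 1 or 3 and 3 without PTCL replicate 2. Without PTCL replicate 2 it was 2 for each of B cell lineage, B cell receptor signalling and NF-kappaB targets, and without LBT replicate 4 it was 1, 1 and 3. Without PTCL replicate 1 it was 1 for the neutrophil list. Single dogs moved medians without ending a call. B cell lineage lay at -2.80 without PTCL replicate 2, -2.62 without LBT replicate 4, -2.59 without PTCL replicate 3 and -1.25 without PTCL replicate 4. Without PTCL replicate 4 the median was -0.97 for B cell receptor signalling, -1.17 for the macrophage list, -0.97 for the neutrophil list and -1.76 for immediate early genes, and without PTCL replicate 3 that of the neutrophil list was -2.86.

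Limma called 51 of 7500 genes between LBT and PTCL, 35 higher and 16 lower in LBT, with 82 when the array set was a block and 69 without its 6 arrays. With sex, breed and age as covariates 4 genes were called and with these 8 dogs alone 0, at 934 genes with an unadjusted p under 0.05 in the fit of all subtypes. Without PTCL replicate 4, the dog of intermediate grade, 11 genes were called, and without PTCL replicate 2 the count was 180.

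The 2 BL dogs were set against the 10 DLBCL dogs. The adaptor SHC3 was higher in BL (log2 6.75 ± 1.95 against 2.90 ± 1.54, SD, limma adjusted p = 0.027), by 5.35-fold with values below the minimum set to it. As measured, its difference was 2.47 without BL replicate 1 (adjusted p = 0.621), 5.23 without BL replicate 2 and 3.78 without DLBCL replicate 11 (adjusted p = 0.0507). COG1, a subunit of a Golgi tethering complex, was 5.44-fold lower in BL (5.64 ± 1.45 against 8.09 ± 0.40, limma adjusted p = 5.68e-05), 11.1-fold without BL replicate 1 and 2.67-fold without BL replicate 2 (adjusted p = 0.226). DNTT had mean log2 values of 7.35 ± 0.63 in BL and 3.79 ± 2.12 in DLBCL, a difference of 3.55 that was not called (adjusted p = 0.337) except without DLBCL replicate 4 (adjusted p = 0.0381). Immediate early genes had a median difference of -1.04 over 16 genes, with -3.80 (SE 0.80) for JUN (adjusted p = 0.114, and 0.0458 without DLBCL replicate 5), and 1 gene passed when adjusted over the list alone. Mitosis genes had a median of 0.89 over 25 genes and DNA replication genes 0.46 over 26, with 0 genes called in either list, over all genes or adjusted over the list alone.

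Camera called the immediate early list at adjusted p = 9.1e-07, mitosis at 6.2e-06 and replication at 4.2e-04, with adjusted p = 0.42, 0.85 and 0.85 with an estimated correlation. By exact permutation of dogs, where 8 of 25 lists would have to reach the smallest possible p of 0.015, the adjusted p was 0.38, 0.61 and 0.61. Without the array set camera also called the immature lymphoid list (adjusted p = 0.020). Limma called 2 of 7500 genes between BL and DLBCL, with 426 at an unadjusted p under 0.05 against 375 by chance, 3 with the array set as a block and 5 without its 6 arrays. With covariates the adjusted p of SHC3 was 0.113, and another probe set of COG1 had a difference of -0.69 (adjusted p = 0.949). With 2 BL dogs, leaving out BL replicate 1 gave 12 genes and BL replicate 2 gave 1 gene, and without BL replicate 2 the replication list was not called (adjusted p = 0.19).

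The last comparison asks whether the step from low-grade to high-grade subtypes differed between the lineages. For B it is DLBCL minus MZL and for T the mean of LBT and PTCL minus TZL. A positive difference means a higher step in B. CCDC3 (6.52, SE 0.71, adjusted p = 4.95e-07) had mean log2 values of 2.80 in DLBCL and 2.97 in MZL, against 3.23 in LBT, 4.98 in PTCL and 10.80 in TZL. TCEA3 (6.17, SE 0.98), GLYAT (5.86, SE 0.65), RBP4 (5.58, SE 1.73) and the glycogen phosphorylase PYGL (5.09, SE 1.19) also had a higher step in B. DPP4 (-6.17, SE 0.70, adjusted p = 8.2e-07) lay at 3.38 in DLBCL and 3.25 in MZL, against 11.65 in LBT, 9.96 in PTCL and 4.50 in TZL. SMOC2 (-6.55, SE 0.86), AMPH (-6.28, SE 0.95), ANK3 (-5.97, SE 0.90) and NSG1 (-5.71, SE 0.80) likewise had the lower step in B. Most of these differences rest on groups below the minimum intensity, such as SMOC2, AMPH, ANK3 and NSG1 in TZL, GLYAT in LBT and PTCL and RBP4 in LBT, and are not exact. With values below the minimum set to it, they were 6.06 for CCDC3, 5.89 for TCEA3, 3.92 for GLYAT, 5.13 for RBP4, 4.51 for PYGL, -6.15 for DPP4, -5.08 for SMOC2, -4.80 for AMPH, -4.41 for ANK3 and -4.49 for NSG1, with adjusted p of 0.0377 for RBP4 and of 0.00869 or smaller for the others. As measured, without PTCL replicate 4 the difference was -7.26 for SMOC2, -7.06 for AMPH, -6.68 for ANK3 and -6.53 for NSG1, and without PTCL replicate 2 it was -5.93 for SMOC2 and -5.65 for AMPH. PYGL was at 4.45 without MZL replicate 3 and 6.14 without MZL replicate 5, and RBP4 at 6.34 without MZL replicate 2 and 6.31 without TZL replicate 9.

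Camera called 4 lists for the difference between the steps. None held with an estimated correlation. Permutation of dogs removes subtype differences and cannot test whether steps differ (adjusted p = 0.34 for mitosis and interferon response, 0.21 for the others). With the 3' to 5' controls as covariates camera also called MHC class II (0.62, adjusted p = 0.038). Mitosis genes differed by a median of -1.65, with 5 of 25 called and 12 when adjusted over the list alone. The number called was 2 without MZL replicate 2 or 5, 3 without any of 5 dogs (MZL replicate 3, DLBCL replicate 9, PTCL replicate 3 and TZL replicates 1 and 4), 8 without TZL replicate 9 and 9 without PTCL replicate 2. Among them were CCNE2 (-2.58, SE 0.48) and KIF11 (-2.39, SE 0.69). DNA replication genes differed by -0.79, with 6 of 26 called and 12 when adjusted over the list alone, such as MCM5 (-2.69, SE 0.45). Cytotoxic and NK genes had a median of 2.21, with 2 higher and 1 lower of 14, 7 and 1 when adjusted over the list alone, including FASLG (4.63, SE 0.67), and interferon response genes one of 2.12, which was 1.13 without MZL replicate 1 (camera adjusted p = 0.031), with USP18 (3.41, SE 0.97) as the 1 gene of 15 called, over all genes and adjusted over the list alone. The camera adjusted p was 3.7e-08 for mitosis, 7.4e-07 for replication, 5.3e-05 for the cytotoxic list and 4.4e-04 for interferon response, with adjusted p = 0.57, 0.55, 0.55 and 0.67 with an estimated correlation. PTPRC had a difference of -2.78 (adjusted p = 0.0596), CD4 one of -3.0 (0.0605) and CD8A one of 3.78 (0.0585). Only TZL's CD8A mean reached the minimum, so 3.78 is not exact. Leaving out 1 dog brought PTPRC under 0.05 in 5 of 32 cases, CD4 in 4 and CD8A in 4. PTPRC was at -2.07 without TZL replicate 5 (0.00712). USP18 lost its call without MZL replicate 1 (2.42, adjusted p = 0.0766) or 3 (0.0636). Without MZL replicate 2 the interferon genes called were 2. KIF11 lost its call without MZL replicate 2 or 5 (adjusted p = 0.0702 and 0.0619).

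Limma called 555 of 7500 genes for the difference between the steps, 198 with the higher and 357 with the lower step in B. With the array set as a block 595 genes were called, without it 313, and with sex, breed and age as covariates 343. RBP4 lost its call under each of these 3 settings (adjusted p = 0.074, 0.246 and 0.282), and in 19 of 32 cases of 1 dog left out (adjusted p up to 0.0896), and PYGL lost it with the covariates (adjusted p = 0.0641).

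**Figure D4:**
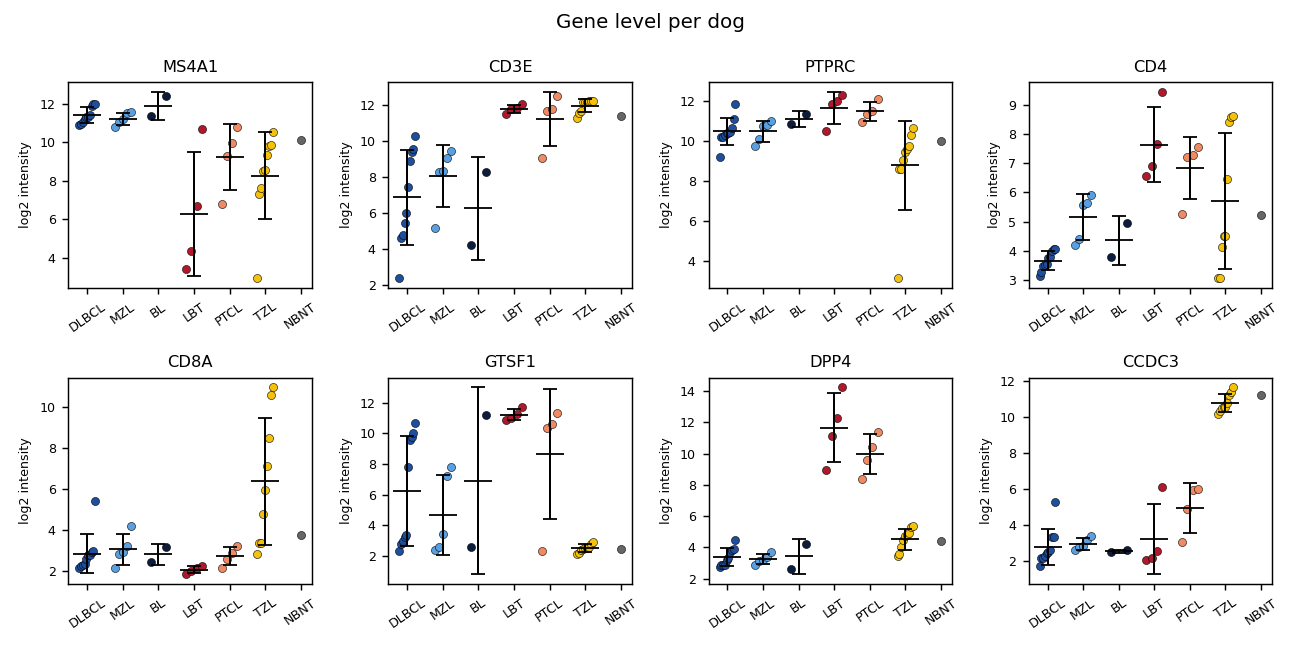
Log2 intensity (vertical) of 8 genes in each dog by subtype (horizontal), with mean ± SD bars and the NBNT dog as a single point. CCDC3 lies at 10.2 or higher in all TZL dogs and at 6.11 or lower in the other tested dogs, while DPP4 lies at 8.40 or higher in LBT and PTCL and at 5.37 or lower in the other subtypes.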

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

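The tests of RNA degradation, of the hybridisation controls, of a swap of samples, of a faulty probe set and of fewer leukocytes were chosen only after the result each bears on was seen.

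The set of 6 arrays that stands apart on the actin 3' control and on the third component spans DLBCL, PTCL and TZL dogs. RNA degradation cannot be told apart from other causes. The difference between 3' and 5' probe sets was larger in the set for actin (by 4.07), but the actin 3' control defined the set. It was not larger for GAPDH (difference -0.24, exact permutation p = 0.26). The bioB and bioC controls, which are added to each hybridisation and do not depend on the tumour's RNA, were 1.17 higher in the set (8.52 ± 0.51 against 7.35 ± 0.50, exact permutation p = 5.3e-05), whereas bioD and cre controls, read after these, differed by -0.73 to -0.09. The set's shift correlated at 0.613 across genes (not independent replicates) between B and T subtypes, against -0.246 to 0.320 for 100 drawn sets. Drawn sets were not picked as extreme, so this decides nothing. A separate array or labelling batch is a candidate, though not all controls moved the same way. No biological cause was tested, as no label sets these dogs apart.

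A probe set that separates the sexes, annotated as EIF2S3, opposed the sex label in MZL replicate 2, a female with a log2 value of 10.5, and in PTCL replicate 3, a male with 1.63. A swap of these samples with each other is argued against by their lineage scores, where B minus T was 3.70 in the MZL dog and -4.38 in the PTCL dog, each on the side of its labelled lineage. A wrong sex in the labels could not be decided. A score of 11 X-linked genes that escape inactivation differed by 0.282 between 18 females (7.91 ± 0.31) and 14 males (7.62 ± 0.24, SD, permutation p = 0.0098), with 7.59 in the MZL and 8.14 in the PTCL dog, but the sexes overlapped from 7.23 to 8.13. No biological explanation was tested.

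PTPRC, which encodes CD45, was lower in TZL (8.81 ± 2.24, range 3.14 to 10.7, n = 9) than in LBT and PTCL together, by 2.78 (exact permutation p = 0.00021). Without TZL replicate 5 the limma difference was 1.98 for PTCL and 2.16 for LBT, and without PTCL replicate 2 that of PTCL was not called (2.48, adjusted p = 0.0678). A fault of 1 probe set is argued against by all 3 probe sets of the gene, whose smallest difference was 2.78, with 3.00 and 3.58 for the others. Fewer leukocytes in TZL tissue are argued against by the T cell lineage score, which differed by -0.158, and scaling between arrays by differences of 2.73 to 2.80 under 3 other scalings. A lower CD45 level may therefore be a property of the TZL tumours, as a hypothesis found and tested on the same data, and grade, which goes with subtype, stays open as untested.

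Of 180 tests for a dog far from the rest of its subtype, 20 found one, against about 9 by chance. DLBCL replicate 3 had the highest list scores of its subtype for cytotoxic and NK genes (8.26, next 5.76), germinal centre genes (8.56, next 6.36) and T cell co-inhibition (5.27, next 4.15), the lowest for MYC targets (9.19, next 9.71), and the highest CD8A (5.42, next 2.99). TZL replicate 5 was lowest of its subtype for germinal centre genes (4.05, next 5.71), the follicle list (4.17, next 5.64), MS4A1 (2.91, next 7.28) and PTPRC (3.14, next 8.61). PTCL replicate 4 was lowest for the T cell lineage list (7.01, next 8.84) and CD4 (5.24, next 7.20), and MZL replicate 1 for the immature lymphoid list (3.60, next 4.37) and CD3E (5.14, next 8.30). Stroma genes were high in DLBCL replicate 11 (7.61, next 5.13), MZL replicate 2 (6.89, next 3.55) and TZL replicate 6 (6.08, next 4.52). The remaining 4 were NF-kappaB targets in LBT replicate 4 (7.11, next 5.80), the p53 list in PTCL replicate 3 (6.29, next 6.94), immediate early genes in TZL replicate 1 (11.2, next 9.50) and DNTT in PTCL replicate 1 (3.08, next 2.41).

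The grade steps of the lineages differed by the limma test of the difference in 555 genes, with differences as measured, which rest in part on groups below the minimum intensity, of 6.52 for CCDC3, 6.17 for TCEA3, 5.86 for GLYAT, 5.58 for RBP4, 5.09 for PYGL, -6.55 for SMOC2, -6.28 for AMPH, -6.17 for DPP4, -5.97 for ANK3 and -5.71 for NSG1. Without PTCL replicate 4 these were -7.26 for SMOC2, -7.06 for AMPH, -6.68 for ANK3 and -6.53 for NSG1, and without PTCL replicate 2 -5.93 for SMOC2 and -5.65 for AMPH. PYGL was at 4.45 without MZL replicate 3 and 6.14 without MZL replicate 5, and RBP4 at 6.34 without MZL replicate 2 and 6.31 without TZL replicate 9, with its call lost in 19 of 32 cases of 1 dog left out (adjusted p up to 0.0896). By camera they differed in cytotoxic genes (median 2.21), mitosis (-1.65), DNA replication (-0.79) and interferon response (2.12, and 1.13 without MZL replicate 1). None held with an estimated correlation (adjusted p = 0.55, 0.57, 0.55 and 0.67). Permutation of dogs (adjusted p = 0.21, 0.34, 0.21 and 0.34) and splits (77 of 100 called as many) cannot test whether steps differ. Of 4328 unnamed probe sets passing the filter, limma called 1888 between B and T, 894 higher and 994 lower in B.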

How the results depend on the processing

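The settings with the array set, with bright probe sets, with values below the minimum set to it, with the 3' to 5' controls as covariates and without the 2 dogs of opposed sex probe set were chosen only after the data were seen. Where the main or new fit called a named gene, 2 signs turned, both between B and T. PTPRC lay at -1.07 among high-grade dogs (adjusted p = 0.00919) and MYC at -0.41 within the array set (0.769). The gap between B and T on the first component, taken without its sign, kept a permutation p = 1e-05 under quantile normalization, the stricter filter and without the array set. The median of all genes lay between -0.12 and 0.14 in every comparison under the 3 other scalings. The cause of each change below was not tested, except where fewer or more genes or dogs were tested by construction.

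For B against T the count of genes was 1435 at 2-fold or more, 7870 over every probe set and 149 within the array set, and of lists 2 with an estimated correlation and 14 by permutation. For DLBCL against MZL the count of genes, 0 in limma with 977 at an unadjusted p under 0.05, was 17 with the stricter filter, 378 with array weights, 9 over every probe set, 10 with the mean of a gene's probe sets, 20 with both arrays of the repeated case, 6 in Golden Retrievers, 5 with centring on bright probe sets, 39 with values below the minimum set to it, 19 without the array set and 16 without the 2 dogs of opposed sex probe set, and of lists 14 in Golden Retrievers and 0 with an estimated correlation. For PTCL against TZL it was 2267 over every probe set, 556 without the array set and 679 without the 2 dogs of opposed sex probe set, and of lists 0 with an estimated correlation and 4 by permutation. For LBT against TZL it was 5199 over every probe set, and of lists 0 with an estimated correlation. For LBT against PTCL it was 33 with the stricter filter, 146 over every probe set, 4 with covariates, 0 with the compared groups only, 11 without the dog of intermediate grade, 96 with values below the minimum set to it, 82 with the array set as a block and 81 without the 2 dogs of opposed sex probe set, and of lists 0 with an estimated correlation and 0 by permutation. For BL against DLBCL it was 6 without a filter, 1 each with the stricter filter, quantile normalization and the mean of a gene's probe sets, 12 with array weights, 6 over every probe set, 11 with values below the minimum set to it, 6 with the 3' to 5' controls as covariates, 5 without the array set and 1 without the 2 dogs of opposed sex probe set, and of lists 5 with the compared groups only, 0 with an estimated correlation and 0 by permutation. For the difference between grade steps it was 1320 over every probe set, 343 with covariates and 313 without the array set, and of lists 0 with an estimated correlation and 1 by permutation.

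Leaving out 1 dog at a time gave 3326 to 3526 genes and 7 to 9 lists for B against T, 1745 to 2223 genes and 11 to 14 lists for LBT against TZL, and 426 to 654 genes and 4 to 6 lists for the grade steps. For DLBCL against MZL it gave 0 to 68 genes, with 68 without DLBCL 3, 43 without DLBCL 10, 15 without MZL 2, 5 without DLBCL 8, 4 without DLBCL 9, 2 without MZL 1 or MZL 5 and 1 without DLBCL 11, and 5 to 11 lists, with 5 without DLBCL 6 or MZL 4. For PTCL against TZL it gave 587 (without PTCL 2) to 1085 genes and 6 to 8 lists. For LBT against PTCL it gave 11 to 180 genes, with 11 without PTCL 4, 30 without LBT 2, 85 without PTCL 3, 96 without LBT 4 and 180 without PTCL 2, and 10 to 13 lists. For BL against DLBCL it gave 1 to 12 genes, with 12 without BL 1, 7 without DLBCL 5, 5 without DLBCL 4 and 1 without BL 2 or DLBCL 11, and 3 to 7 lists, with 7 without BL 1 and 6 without BL 2. Where 1 BL dog remained, it was assumed to vary like the other groups. Golden Retrievers alone were planned only where every group keeps at least 2 dogs, so this was not run for the comparisons with BL or PTCL or for the grade steps. Genes near the minimum intensity limit every fold given as a bound.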

Other observations

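The relation of CD4 to CD8A and the nearness of the NBNT dog to TZL were tested only after these values had been seen. Single genes of other cell types and of metabolism differed between the phenotypes, while the lists they belong to were not called by camera. Of this paragraph's lists permutation called only neutrophil and mast cell genes. CMA1, the mast cell chymase, was below the minimum in every B dog and at least 8.52-fold lower there (limma adjusted p = 5.7e-05), although the neutrophil and mast cell list was not called by camera (adjusted p = 0.15) and was lower in B by permutation of dogs (adjusted p = 0.0039). The complement gene C1QA (1.99, SE 0.66) and the myeloid and B cell factor SPI1 (1.52, SE 0.39) were higher in B, while CD80 was lower (-2.47, SE 0.54), within a macrophage and dendritic cell list that was not called (adjusted p = 0.93). The matrix gene FBN1 was higher in B (3.54, SE 0.52), THY1 was lower (-2.40, SE 0.55), and CXCL12, below the minimum in every B dog, was at least 1.23-fold lower, with a stroma list median of -0.44 at camera adjusted p = 0.68. Glycolytic isoforms moved apart, with PFKL higher in B (2.34, SE 0.37) and ENO2 (-2.51, SE 0.41) and ALDOC (-2.26, SE 0.38) lower, at adjusted p = 0.96 for the list.

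Regulators of survival and of the cell cycle differed as single genes. BCL2L1, an apoptosis inhibitor, was lower in B (-1.71, SE 0.28, adjusted p = 8.42e-06), as were the cyclin-dependent kinase inhibitor CDKN2C (-2.97, SE 0.42) and the kinase PLK3 (-2.29, SE 0.24), while SESN1, a p53 target, was higher (2.42, SE 0.38). The lists of cell death regulators (adjusted p = 0.41) and of tumour suppressors and p53 targets (adjusted p = 0.93) were not called by camera, though by permutation of dogs both were called with lower scores in B (adjusted p = 0.034 and 0.015). The step in grade was lower in B for IKZF2 (-4.62, SE 0.71), TOX (-3.26, SE 0.46) and MYB (-3.13, SE 0.58) with values below the minimum set to it, since the DLBCL and MZL means of all 3 lay below it, although no list they belong to was called by camera as measured. The co-inhibition list of IKZF2 and TOX had adjusted p = 0.11, 0.038 with those values set to the minimum and 0.55 with estimated correlation. Permutation gave 0.0032 but cannot test whether steps differ. The immature lymphoid list of MYB had a median of 1.20, opposite to MYB, with camera adjusted p = 0.85.

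The NBNT dog correlated across genes with the 9 TZL dogs at 0.932 to 0.978 and with no other dog above 0.926, so that 9 of 9 TZL dogs were closer to it than every dog of the other subtypes. Its log2 values were 11.3 for CCDC3, 4.39 for DPP4, 10.1 for MS4A1 and 11.4 for CD3E. These values are consistent with a tissue close to TZL in expression, from a single dog.

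A hypothesis tested on the 9 TZL dogs was that their PTPRC signal may come from other leukocytes of the node. PTPRC correlated with the B cell lineage score at Pearson r = 0.886 (exact permutation p = 0.00018, adjusted p = 0.00054 over 3 relations) and Spearman rho = 0.967 (exact p = 0.00017, adjusted p = 0.00051), with r = 0.850 without TZL replicates 3 and 5 and 0.914 over the 6 dogs outside the array set. With the macrophage score r was 0.775 (exact permutation p = 0.0061, adjusted p = 0.0092) and rho 0.700 (exact p = 0.043, adjusted p = 0.064), with r = 0.632 without TZL replicates 1 and 5 and 0.928 outside the array set. CD4 and CD8A correlated at r = -0.595 (exact permutation p = 0.094, adjusted p = 0.094) and rho -0.483 (exact p = 0.19, adjusted p = 0.19), with r = -0.566 without TZL replicates 3 and 8 and -0.608 outside the set, so whether each tumour is of a single T cell subset could not be decided. The set held 3 of the 9 dogs, too few for a value within it.

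Other splits of the dogs into groups of the same sizes, with the real split counted, tested whether chance can be excluded. It can for the genes of B against T, PTCL against TZL and LBT against TZL. In that order 1 of 100 splits reached 3486, 1025 and 2259 genes (highest other 956, 598 and 791). For the grade steps 1 of 100 reached 555 (highest other 4), with dogs reassigned within lineages. This removes all subtype differences and cannot test whether steps differ, for genes or lists. Chance cannot be excluded for the genes of LBT against PTCL, where 6 of 35 splits reached 51 (highest other 149, several times that). Whether 149 reflects a structure among these 8 dogs was not tested. Leaving out single dogs gave 11 to 180. For DLBCL against MZL the splits decide nothing about genes, because all 100 reach the real 0 by construction (highest other 33). Chance cannot be excluded for the number of lists called by camera, where 45 of 100 splits reached 8 for B against T (highest other 18), 11 of 100 reached 9 for DLBCL against MZL (17), 48 of 100 reached 7 for PTCL against TZL (17), 15 of 100 reached 12 for LBT against TZL (17), 3 of 35 reached 12 for LBT against PTCL (14) and 77 of 100 reached 4 for the grade steps (16).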
